A study of Mus musculus with 12 samples.

How the data were processed

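RNA was extracted from flash-frozen, dissected lung tumour of the Rb1, Trp53 and Myc mouse model, and libraries were made with poly(A) selection and an Illumina kit, per the labels' protocols. The 12 libraries were grouped by their titles into control, anti-PD-1, entinostat and combination, 3 each. The treatment tag of the combination libraries names the antibody alone while their titles name both agents, and the title was followed. Each library carries the batch label 2, so no batch could be compared. Per the labels' protocols, methylcellulose and an isotype antibody served as controls, and the labels do not say which of these the control libraries received.

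The values are raw counts per gene, deposited by the authors as a single table with 22738 gene rows and a column for each of the 12 libraries. Every column was used. Trim Galore, Trimmomatic 0.36, STAR 2.5.4a, DESeq2 1.22.2, R 3.5.1 and the mouse build mm9 are named in the submitters' processing notes. The gene annotation, the strand setting, the handling of reads that map to several places and the parameters of each step are not given in the sources used here. Genes with near-identical copies or processed pseudogenes, such as histone genes, Nme1, Ran and Mt1, are therefore uncertain, as are antisense, overlapping and small RNA genes. The annotation at hand is of another build, so no coordinates are given. In the table, 455 rows carry a numbered suffix for a further locus of the same symbol and were kept as separate rows. Of the values, 35 of the largest are written with 6 significant digits, so their last digits are rounded. Among counts from 1 to 20, between 65.3% and 77.2% per library are even numbers. Both mates of a read pair may therefore have been counted, and totals may overstate the number of fragments; refitting with halved counts was added as an alternative.

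Total counts ranged from 31295987 to 54001886 per library. At this depth a well expressed gene has little counting error, and the spread between libraries sets the precision. None of the 66 pairs of libraries agreed within sampling noise (chi-square per degree of freedom of at least 32.6, for entinostat library 2 and combination library 1, whose log2 CPM correlation of 0.975 was the highest of all pairs), which excludes a library deposited in 2 copies but not libraries made from the same mouse or tumour. Each was counted as a sample, as the labels list them.

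Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 17426 genes, library sizes were scaled with TMM factors, and a model with a mean per group was fitted to all 12 libraries, so that the groups shared an estimate of the spread. The quasi-likelihood F test with robust estimation gave log2 fold changes, standard errors and p-values, adjusted by Benjamini-Hochberg within each of 8 comparisons with a threshold of 0.05. The comparisons were entinostat, anti-PD-1 and the combination against control, the combination against each single treatment, the main effects of entinostat and of anti-PD-1, and their interaction. A main effect is the mean of the treatment's effects without and with the other agent, so that its log2 fold change need not equal the ratio of the 2 pooled means. CPM values are scaled by TMM factors, and each is given as mean ± SD over libraries. A log2 CPM uses a prior count of 2. Splits of 3 against 3 libraries number 10, so a permutation p cannot go below 0.1.

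Before the data were examined, 35 gene lists were fixed for tumour subtypes, signalling, immune and other cell types, and the drug's targets. Lists with at least 5 tested members, 34 in number, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation as an alternative and with fry. Also fixed beforehand was the rule for naming genes. Per comparison it takes the 10 largest rises and 10 largest falls by log2 fold change among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups, skipping predicted genes and immunoglobulin or T cell receptor segments. From each list it takes up to 4 members past the threshold by smallest adjusted p, or else up to 2 with the highest expression. It always includes Myc, Rb1, Trp53, Hdac1, Hdac2, Hdac3, Pdcd1, Cd274, Neurod1, Pou2f3, Yap1 and Cdkn1a. Where no gene passes, it takes the 3 smallest p-values. A subset is given here in the order of the rule, and some genes it takes are not reported here; for genes that did not pass, mostly CPM values and no fold change are given, a choice made after their values were seen.

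The scripts were tested on simulated data with 200 changed genes among 17426, in 5 sets. For entinostat against control, 4.4% of genes changed 2-fold and 41.4% of genes changed 4-fold were recovered, and 5.76% of calls were false. For the entinostat main effect, 21.8% and 67.2% were recovered and 5.32% of calls were false. Genes that did not pass may thus have changed, above all by 2-fold or less. The simulated genes were drawn independently, with the same mean in all libraries apart from the changed genes. The sets thus held no difference in tissue makeup or structural RNAs, and the false share need not hold for these libraries.

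Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper quartile factors, no filter on low counts, the replicate number as a block, voom with sample quality weights, the mean log2 CPM of the alveolar markers as a covariate, only the 2 groups compared, and leaving out each library in turn. Added after seeing the data were fits without the 3 structural RNAs, with their percent of reads as a covariate, with high Xist as a covariate, with halved counts, with counts thinned to equal depth over all tested genes or over those other than the structural RNAs, and with trends on gene length and GC content removed. For the last, the length and GC content of the longest transcript per symbol in GENCODE vM21 were found for 16648 of 17426 genes, 1774 of the 1849 called for the entinostat main effect among them. A spline of each library's deviation from the mean log2 CPM on both was then subtracted as an offset, centred so that the scaling between libraries stayed. The centring was added after a first form without it had been run.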

Results

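Gene expression was measured by RNA-seq in lung tumours of a genetically engineered mouse model of small cell lung cancer, a neuroendocrine tumour. In this model a Cre virus delivered to the airway, with expression driven by the promoter of a neuroendocrine gene, deletes the tumour suppressors Rb1 and Trp53 and switches on a mutant Myc allele. Mice with tumours visible on magnetic resonance imaging were assigned at random, balanced on tumour volume, to 4 treatments. Entinostat, an oral inhibitor of class I histone deacetylases (HDACs), was given at 15 mg/kg daily for 28 days. An antibody against PD-1, an inhibitory receptor of T cells, was given at 10 mg/kg for 4 weeks. A combination group received both agents, and a control group received neither. The control libraries are named only as control, so whether these mice received the oral vehicle, an isotype antibody or both is not given in the sources used here. The 12 libraries comprised 3 per group and carried a single batch label. Total counts per library ranged from 40534618 to 54001886 in the control group, from 34107018 to 37076865 with anti-PD-1, from 31987261 to 40469275 with entinostat and from 31295987 to 36146798 with the combination. The column headers carry a different long number for each library, but its meaning is not given in the sources used here. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples.

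The libraries differed in composition as well as in treatment. Rpph1, Rn45s and Rmrp, abundant structural RNAs without a protein product, took 11.4% ± 3.08 of the reads in the control group, 27.5% ± 8.15 with anti-PD-1, 17.8% ± 2.22 with entinostat and 17.9% ± 0.17 with the combination (SD, n = 3 each). Markers of alveolar epithelium, the lining of the normal lung, had a mean log2 CPM (read counts scaled to a common library size) of 1.29 ± 2.68 in the control group, 2.85 ± 1.96 with anti-PD-1, 4.15 ± 0.80 with entinostat and 3.79 ± 1.49 with the combination (SD, n = 3 each). Airway epithelial markers stood at 0.89 ± 2.80, 1.85 ± 2.16, 2.46 ± 0.29 and 1.74 ± 1.06 in the same order. Macrophage and monocyte markers stood at 1.69 ± 1.04, 2.28 ± 0.52, 2.63 ± 0.57 and 2.90 ± 1.20. Control library 1 lay far from the others on the first principal component, which held 27.2% of the variance, and had the lowest alveolar score of the 12 libraries. Xist, expressed in female cells, lay between 1111 and 4953 CPM in control library 3, anti-PD-1 libraries 1 and 2, entinostat library 1 and combination libraries 2 and 3, and lay between 0.27 and 2.05 CPM in the other libraries.

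**Figure D1:**
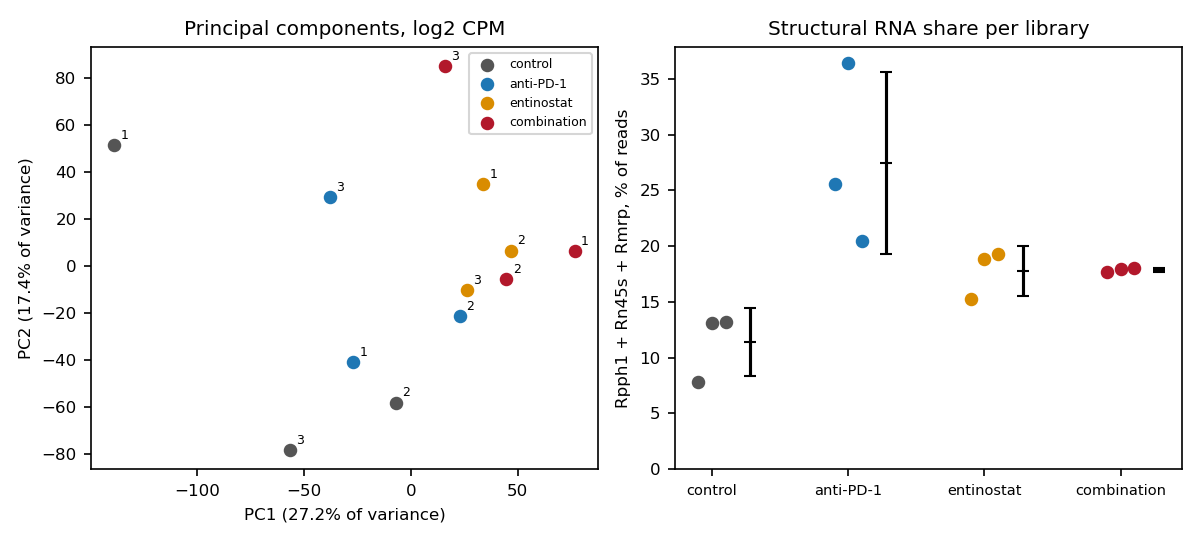
Left, principal components of log2 CPM over the 17426 tested genes, with 1 point per library, labelled by replicate number and coloured by group (PC1 27.2% and PC2 17.4% of the variance). Right, percent of reads from Rpph1, Rn45s and Rmrp per library, with group mean and SD as bars; the anti-PD-1 libraries lie highest, at 27.5% ± 8.15.

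The induced alleles were examined first. Rb1 stood at 41.9 ± 10.4 CPM in the control group, 66.1 ± 14.5 with anti-PD-1, 38.7 ± 12.1 with entinostat and 43.5 ± 9.49 with the combination (SD, n = 3 each). Trp53 stood at 16.5 ± 3.31, 12.5 ± 5.68, 12.2 ± 1.5 and 14.1 ± 0.73 CPM in the same order. Bulk tumour tissue contains other cells that carry intact alleles, and gene-level counts do not separate the deleted part of a gene from the rest, nor the mutant Myc allele from the endogenous one. Myc stood at 80.7 ± 26.3 CPM in the control group, 114.7 ± 44.9 with anti-PD-1, 233 ± 45.9 with entinostat and 193 ± 30.6 with the combination.

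The effect of entinostat, taken over mice with and without the antibody, was tested by comparing the 6 libraries with entinostat and the 6 without. Myc rose, with a log2 fold change of 1.14 (SE 0.22, edgeR adjusted p = 0.014, n = 6 and 6), from 97.7 ± 37.8 to 213 ± 41.4 CPM (SD). Yap1, a transcriptional coactivator of the Hippo pathway, rose by 1.74 (SE 0.39, adjusted p = 0.021) from 5.63 ± 3.17 to 18.6 ± 8.41 CPM. Of the neuroendocrine list 4 of 19 genes fell and of the neuronal differentiation list 3 of 19, among them Stmn3, a microtubule regulator of neurons (−1.99, SE 0.28), Scg5, a chaperone of secretory granules (−1.88, SE 0.25), and Elavl4, a neuronal RNA-binding protein (−1.34, SE 0.27). Several cell cycle genes fell too, including Pcna, the sliding clamp of DNA replication (−0.98, SE 0.16), and Cdk1, the mitotic kinase (−0.83, SE 0.15). In all, 1849 of 17426 tested genes changed, 674 higher and 1175 lower. Scaling by upper quartile factors instead of TMM (trimmed mean of M values) called 1046 higher and 632 lower, so which direction held more genes depended on the scaling. That scaling moved the median log2 fold change of all tested genes from 0.02 to 0.15.

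The largest rises among genes whose 6 and 6 libraries did not overlap were in Ccnb1ip1, a ubiquitin ligase named for its binding to cyclin B (4.34, SE 0.62), Ddn, a postsynaptic protein (3.39, SE 0.75), Sfrp2, a secreted Wnt modulator (3.10, SE 0.52), Bmp8b (2.87, SE 0.45), Trpv4, a cation channel (2.87, SE 0.56), Adamts14 (2.82, SE 0.39) and Itpr3, an intracellular calcium channel (2.79, SE 0.36). Itpr3 went from 6.86 ± 4.56 to 45.2 ± 23.5 CPM. The largest falls under the same rule were in Zfp951 (−2.21, SE 0.53), Slc45a1 (−2.18, SE 0.59), Lrrtm4, a synaptic adhesion protein (−2.08, SE 0.43), Stmn3, Gamt, an enzyme of creatine synthesis (−1.88, SE 0.28), and Scg5. Stmn3 went from 187 ± 117 to 44.4 ± 8.87 CPM and Scg5 from 97.1 ± 31.3 to 26.5 ± 9.10 CPM.

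Among the fixed gene lists, 4 of 19 genes of the neuroendocrine list fell and none rose. Besides Scg5 these were Uchl1, a neuronal ubiquitin hydrolase (−1.15, SE 0.27), Calca, the calcitonin gene (−2.75, SE 0.76), and Scg2, a granin (−2.39, SE 0.67); 5 fell when adjusted over the list alone. Of 19 neuronal differentiation genes 3 fell, Stmn3, Elavl4 and the dendritic microtubule protein Map2 (−1.15, SE 0.29), or 6 adjusted over the list alone. Of 13 YAP1 and TEAD genes 4 rose (8 adjusted over the list alone): Yap1, Cyr61, a secreted matricellular target (1.06, SE 0.26), the transcription factor Tead1 (0.65, SE 0.17) and Ajuba (1.30, SE 0.36). Of 14 Notch pathway genes 3 rose, the ligand Jag2 (0.81, SE 0.14) and the receptors Notch2 (1.46, SE 0.31) and Notch3 (1.00, SE 0.29), and the same number passed when adjusted over the list alone. Of 13 mesenchymal transition genes 2 rose, Itga5 (1.36, SE 0.30) and fibronectin, Fn1 (1.32, SE 0.36), or 4 adjusted over the list alone. Of 15 fibroblast and matrix genes 3 rose, the collagens Col6a1 (1.09, SE 0.22) and Col5a1 (1.20, SE 0.30) and the receptor Pdgfra (1.18, SE 0.33), or 6 adjusted over the list alone. Under upper quartile factors 7 YAP1 and TEAD genes, 5 fibroblast and matrix genes and 3 mesenchymal transition genes rose, and 3 of the neuroendocrine list fell. Alveolar markers moved with these groups, at a median log2 fold change of 0.85 over 16 genes, of which none passed the test, and longer transcripts lay higher, with a median log2 fold change of −0.10 in the quartile of genes with the shortest transcripts and 0.16 in that with the longest.

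Of 24 cell cycle genes 8 fell and none rose, with Pcna, Cdk1, the mitotic activator Cdc20 (−0.72, SE 0.14) and the mitotic regulator Birc5 (−0.60, SE 0.12) at the smallest adjusted p; adjusted over the list alone, 11 fell and 1 rose. While Myc rose, 4 of 22 genes of the MYC and ribosome biogenesis list fell and none rose: Cdk4, a kinase of the G1 phase (−0.91, SE 0.15), Nme1 (−0.95, SE 0.20), Mrto4, a ribosome assembly factor (−0.68, SE 0.17), and the nuclear transport GTPase Ran (−0.55, SE 0.14). With anti-PD-1 alone against control the median log2 fold change was −0.60 for the MYC list and −0.51 for the cell cycle list, against −0.47 and −0.61 with entinostat alone; no member passed with anti-PD-1, and camera's call of both lists there was lost with an estimated correlation (adjusted p = 0.490 each). For the combination against anti-PD-1 the medians were −0.09 and −0.32. Cdk4 lay between 232 and 296 CPM with anti-PD-1 alone and between 165 and 267 CPM in the 6 libraries with entinostat. Under upper quartile factors 6 cell cycle and 2 MYC list genes fell, and Mrto4 and Ran no longer passed. Of 16 cholesterol and fatty acid synthesis genes 3 fell, Idi1 (−0.98, SE 0.18), Insig1 (−0.84, SE 0.17) and Fdps (−1.03, SE 0.25), while the regulator Srebf1 rose (0.51, SE 0.14); adjusted over the list alone, 7 fell and 2 rose. Of 19 genes of MHC class I presentation 3 fell, Calr (−0.61, SE 0.12), Pdia3 (−0.42, SE 0.12) and Psme2 (−0.89, SE 0.24); Calr and Pdia3 are chaperones of the endoplasmic reticulum with many clients, Psme2 is a proteasome activator subunit, and no class I heavy chain passed the test. Under upper quartile factors Calr alone of these 3 still passed. Pdia3 lay between 188 and 215 CPM with anti-PD-1 alone, between 174 and 213 in the libraries with entinostat and between 291 and 397 in the control group. Calr lay between 228 and 261, 198 and 238, and 348 and 531 CPM in the same order. Both were thus below control without entinostat too. Psme2 lay between 35.1 and 47.1 CPM with anti-PD-1 alone, within the control range of 34.5 to 83.8. Jun, an immediate early transcription factor, fell by 1.01 on the log2 scale (SE 0.15).

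The drug targets Hdac1, Hdac2 and Hdac3 and the subtype regulator Neurod1 did not pass the test. Hdac1 averaged 76.1 ± 19.2 CPM without and 71.1 ± 8.84 with entinostat, Hdac2 169 ± 57.8 and 118 ± 10.3, and Hdac3 90.5 ± 18.5 and 71.1 ± 6.31 (SD, n = 6 each). Neurod1, which marks a neuroendocrine subtype, averaged 115 ± 192 and 46.7 ± 43.7 CPM; without control library 1, at 490 CPM, the first was 40.4 ± 61.2 (n = 5), so that library set which mean was higher. Cdkn1a, a cell cycle inhibitor often raised by HDAC inhibitors, stood at 9.93 ± 6.01 and 9.86 ± 5.69 CPM, and Cd274, which encodes PD-L1, at 3.61 ± 1.24 and 4.86 ± 1.30. Pou2f3, which marks the tuft-like subtype, had at most 12 counts in any library and was not tested. No tested member passed in the lists of T cell markers (median log2 fold change −0.40), cytotoxic and NK cell genes (0.16), interferon response (0.37), MHC class II presentation (0.02), checkpoint genes (0.02), macrophage and monocyte markers (0.69), dendritic cell markers (0.03), B and plasma cell markers (−0.26), endothelial markers (0.46), epithelial genes (0.90), airway markers (−0.28), NEUROD1-type genes (−0.89) or tuft-like genes (1.06). The same held for erythroid (0.25), muscle, heart and adipose (−0.03) and mesothelial markers (0.33). Of the remaining lists, 1 of 6 regulatory T cell genes, 1 of 11 neutrophil markers, 1 of 17 genes often raised by HDAC inhibitors and 1 of 19 histone deacetylases and corepressors rose, and 2 of 17 apoptosis regulators and 1 of 15 hypoxia and glycolysis genes fell. Under upper quartile factors 1 interferon response gene rose, 1 apoptosis regulator fell, and no hypoxia and glycolysis gene fell while 1 rose; under RLE factors none of the 17 genes often raised by HDAC inhibitors passed.

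Each gene was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 17426 genes. As whole lists, 11 of 34 passed camera with a preset correlation and 4 passed fry. None passed camera with an estimated correlation, whose adjusted p over the 11 lay between 0.652 and 0.902. The median and mean log2 fold change differed in sign for the immediate early and stress genes (−0.11 and 0.03) and for the apoptosis regulators (−0.02 and 0.10), and for MHC class I presentation the camera direction was down at a median of 0.30. DESeq2 called 3422 genes, and 974 passed with the replicate number as a block. The count of changed genes fell to 252 with the alveolar marker score as a covariate. All 1849 genes kept their sign there, at a median ratio of the log2 fold change of 0.962. Without combination library 1 the count was 617, without entinostat library 2 it was 734 and without anti-PD-1 library 1 it was 797. Without combination library 3 it was 894, without entinostat library 3 it was 951, without anti-PD-1 library 3 it was 1028 and without entinostat library 1 it was 1200. Of 47 called genes with a fold change given here, 23 passed in every fit that left out a library, Myc, Itpr3, Stmn3, Scg5, Pcna and Cdk1 among them. Other list members held less firmly. Yap1 and Notch2 passed in 10 of the 12 fits and Uchl1 in 7. Calca, Scg2, Ajuba, Fn1, Col5a1, Pdia3 and Psme2 passed in 3, and Tead1, Notch3 and Pdgfra in 2.

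**Figure D2:**
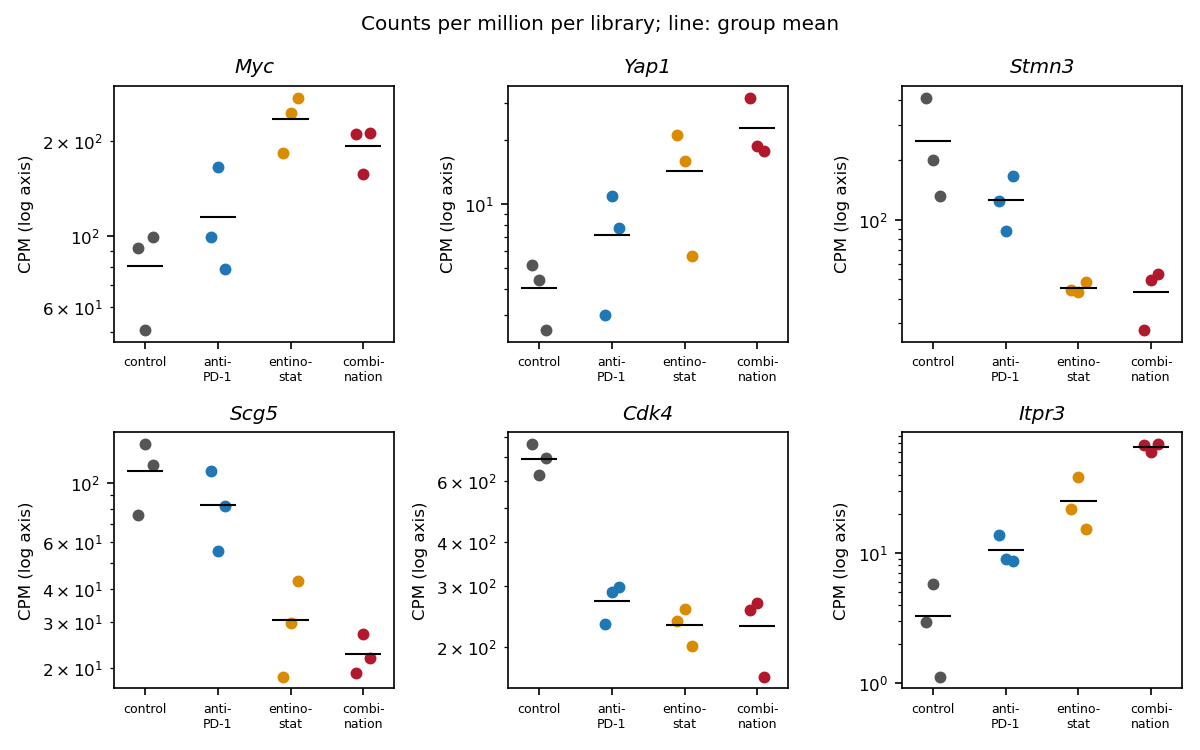
CPM per library on a log axis for Myc, Yap1, Stmn3, Scg5, Cdk4 and Itpr3, with 3 points per group and a line at the group mean. Cdk4 lies between 622 and 763 CPM in the control libraries and at 296 CPM or lower in the other 9, those with anti-PD-1 alone included.

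Entinostat alone was compared with control. Relative to control, Myc rose by 1.53 (SE 0.32, edgeR adjusted p = 0.025, n = 3 and 3). Ccnb1ip1 (4.68, SE 0.90), Evc2 (3.62, SE 0.66), Trpv4 (3.61, SE 0.82) and Evc (3.35, SE 0.72) had the largest rises without overlap between the groups; Evc and Evc2 encode partner proteins of the primary cilium. The largest falls were in Lypd1 (−3.39, SE 0.88), Mb21d2 (−3.05, SE 0.54), the neural adhesion gene Ncam2 (−2.75, SE 0.66) and the receptor tyrosine kinase gene Ret (−2.69, SE 0.50). With anti-PD-1 alone, Evc and Evc2 also lay above every control library, while Ccnb1ip1, Trpv4, Lypd1, Mb21d2, Ncam2 and Ret overlapped the control range. Control library 1 carried much of the fall of Lypd1, at 37.2 CPM against 3.77 and 5.42 in the other controls; without it the log2 fold change was −1.64 (adjusted p = 0.178). Stmn3 fell by 2.45 on the log2 scale (SE 0.41) and Scg5 by 1.88 (SE 0.35). In all, 919 genes changed, 226 higher and 693 lower.

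By list, 6 of 24 cell cycle genes fell and none rose (12 adjusted over the list alone), including Cdk1 (−1.23, SE 0.22), Pcna (−1.22, SE 0.23) and Cdc20 (−0.93, SE 0.20). Of 22 genes of the MYC and ribosome biogenesis list 3 fell (7 adjusted over the list alone), Cdk4 (−1.58, SE 0.21), Nme1 (−1.19, SE 0.29) and the nucleolar methyltransferase Fbl (−0.76, SE 0.18). Jag2 (0.86, SE 0.19), Notch2 (1.71, SE 0.45), Tead1 (1.11, SE 0.25) and Col6a1 (1.57, SE 0.31) rose. With anti-PD-1 alone, Cdk1, Cdc20, Cdk4, Nme1, Fbl, Tead1 and Col6a1 also lay outside the control range, in the same direction. Pcna, Jag2 and Notch2 overlapped the control range there. Fbl lay between 64.1 and 73.1 CPM with anti-PD-1 alone, 76.4 and 90.8 with entinostat, and 119 and 181 in the control group. Yap1 averaged 4.05 ± 1.36 CPM in the control group and 14.3 ± 7.91 with entinostat and did not pass (adjusted p = 0.074). Hdac3 fell by 0.62 (SE 0.15), from 107 ± 8.47 to 69.2 ± 2.86 CPM, and Hdac2 did not pass (adjusted p = 0.079). Mt1, a metallothionein, was the gene of the list often raised by HDAC inhibitors that rose (1.46, SE 0.38; 1 of 17), from 11.9 ± 5.39 to 32.5 ± 12.3 CPM, and stood at 32.5 ± 7.27 CPM with anti-PD-1 alone. Hdac3 stood at 74.3 ± 0.85 CPM with anti-PD-1 alone. The proapoptotic Bax fell (−0.89, SE 0.19; 1 of 17 apoptosis regulators), from 65.5 ± 11.0 to 35.3 ± 3.57 CPM, with 49.0 ± 4.12 CPM under anti-PD-1 alone. Hdac3, Bax, Cdc20, Nme1 and Fbl did not pass under upper quartile factors, which left 2 cell cycle genes and 1 MYC list gene lower. Alveolar markers stood at a median log2 fold change of 1.39 in the same comparison, with none of 16 past the threshold.

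DESeq2 called 2396 genes, and 321 passed with the replicate number as a block. Upper quartile factors called 561 genes, 325 higher and 236 lower, so the direction with more genes turned. No gene passed with the alveolar score as a covariate or when only the 2 groups entered the fit. With the structural RNA percent as a covariate 79 passed, and 515 with trends on gene length and GC content removed. With the alveolar covariate, the 2 groups alone and the structural RNA covariate all 919 genes kept their sign, at median ratios of the log2 fold change of 0.957, 0.980 and 0.889. The count was 2 without entinostat library 3, 42 without entinostat library 2, 204 without entinostat library 1, 250 without control library 1, 550 without control library 2 and 573 without combination library 1, which shares the estimate of the spread, and none of the 24 called genes named in this comparison passed in every such fit. Myc did not pass with the alveolar covariate (log2 fold change 1.75, adjusted p = 0.103), the 2 groups alone (1.56, 0.087) or the structural RNA covariate (1.14, 0.130). Only the last of these lowered the fold change. The adjusted p of Myc ranged from 0.000275 to 0.130 across the fits run. Of 34 lists 9 passed camera with the preset correlation and none with an estimated correlation, at adjusted p between 0.614 and 0.738.

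The combination was compared with control. Relative to control, Myc rose by 1.25 (SE 0.32, edgeR adjusted p = 0.030, n = 3 and 3) and Yap1 by 2.49 (SE 0.56, adjusted p = 0.021). The largest rises without overlap were in Mlxipl, a glucose-responsive transcription factor (6.13, SE 1.34), Ccnb1ip1 (5.32, SE 0.92), the calcium channel gene Cacna1g (5.14, SE 1.51), Alpk1 (4.56, SE 0.87) and Hmcn1 (4.43, SE 0.96). Combination library 3 carried much of the rise of Alpk1, at 152.7 CPM against 13.0 and 20.4, and of Cacna1g, at 73.1 against 12.0 and 4.75; without it their log2 fold changes were 2.66 (adjusted p = 0.041) and 3.30 (0.173), and without control library 1 that of Cacna1g was 9.63, since the other controls held almost none. Among the largest falls were those of Hoxb2 (−4.21, SE 1.02), Opcml (−3.21, SE 0.91) and the transcription factor Sox5 (−3.18, SE 0.61). In all, 2033 genes changed, 677 higher and 1356 lower.

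Neuroendocrine genes that fell were Scg5 (−2.30, SE 0.36) and Uchl1 (−1.64, SE 0.39), 2 of 19. Of 13 YAP1 and TEAD genes 3 rose (7 adjusted over the list alone), Yap1, Tead1 (1.00, SE 0.24) and the kinase Lats2 (1.62, SE 0.43). Of 14 Notch pathway genes 4 rose, Jag2 (1.16, SE 0.19), Notch3 (1.74, SE 0.42), Notch2 (1.75, SE 0.45) and Rest, a repressor of neuronal genes (2.10, SE 0.60). Of 13 mesenchymal transition genes 4 rose, Itga5 (1.79, SE 0.43), Tgfb1 (1.87, SE 0.47), Snai1 (3.29, SE 0.88) and Twist1 (3.82, SE 1.03); the means of Snai1 and Twist1 stayed below 4 CPM. Of 24 interferon response genes 3 rose, Oas2 (3.11, SE 0.91), Irf7 (1.83, SE 0.54) and Irf1, from 5.83 ± 0.52 to 13.5 ± 2.04 CPM. None of these 3 passed in any of the 6 fits that left out a library of either group; without combination library 2, where Oas2 stood at 6.44 CPM and Irf7 at 13.4, their log2 fold changes were 1.71 (adjusted p = 0.195) and 1.08 (0.179). Of 19 genes of MHC class I presentation the regulator Nlrc5 rose (2.57, SE 0.56), while Calr (−1.05, SE 0.18) and Pdia3 (−0.79, SE 0.16) fell. With anti-PD-1 alone each of these genes also lay outside the control range, in the same direction. Of 15 fibroblast and matrix genes 4 rose, with Col6a1 at 1.61 (SE 0.31) and Pdgfra at 2.24 (SE 0.48). Tead1, Lats2, Twist1 and Col6a1 likewise lay above every control library with anti-PD-1 alone. Yap1, Jag2, Notch2, Notch3, Rest, Itga5, Tgfb1, Snai1 and Pdgfra overlapped the control range there. Alveolar markers stood at a median log2 fold change of 1.34 and macrophage markers at 1.01 in the same comparison, with no member past the threshold.

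Of 24 cell cycle genes 9 fell and none rose (15 adjusted over the list alone), including Cdk1 (−1.45, SE 0.22), Cdc20 (−1.23, SE 0.20) and Pcna (−1.34, SE 0.23), and 7 of 22 MYC and ribosome biogenesis genes fell (10 adjusted over the list alone), Cdk4 first (−1.60, SE 0.21). Hdac2 fell by 0.88 (SE 0.22) and Hdac3 by 0.55 (SE 0.15); under upper quartile factors neither passed and 3 other genes of the histone deacetylase and corepressor list rose. The linker histone gene H1f0 fell (−1.35, SE 0.34), which upper quartile factors also ended, and Mt1 rose (1.39, SE 0.38), both from the list often raised by HDAC inhibitors. With anti-PD-1 alone, H1f0 stood at 153 ± 28.4 CPM and Mt1 at 32.5 ± 7.27, next to 149.7 ± 40.7 and 31.1 ± 6.10 with the combination and 383 ± 105 and 11.9 ± 5.39 in the control group, so libraries without entinostat differed from control too. Hdac2 (134.7 ± 3.41 CPM), Hdac3, Cdk1, Cdc20 and Cdk4 also lay below every control library with anti-PD-1 alone, while Pcna overlapped the control range. Cdkn1a averaged 8.18 ± 7.30 CPM in the control group and 12.0 ± 8.07 with the combination, and Cd274 2.91 ± 1.42 and 5.57 ± 1.57, without passing the test.

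DESeq2 called 3591 genes, the fit with the replicate number as a block 1087 and that with the high Xist covariate 1069. Upper quartile factors called 1100 genes higher and 611 lower, so the direction with more genes turned. The count fell to 300 with the alveolar score as a covariate, to 238 with the structural RNA percent as a covariate and to 0 when only the 2 groups entered the fit. In these 3 fits all 2033 genes kept their sign, at median ratios of the log2 fold change of 0.952, 0.879 and 1.01. Without combination library 1 the count was 310, without combination library 3 it was 389 and without control library 1 it was 921. Of 38 called genes named in this comparison 9 passed in every fit that left out a library of either group, while Myc passed in 2 of 6 and Yap1 in 3. Myc did not pass with the structural RNA covariate (log2 fold change 0.87, adjusted p = 0.160) or the alveolar covariate (1.45, 0.071). Nor did Myc pass with the 2 groups alone (1.245, 0.075) or the high Xist covariate (1.223, 0.054). Of these fits, only that with the structural RNA covariate clearly lowered the fold change, next to 1.254 in the main fit. The adjusted p of Myc ranged from 0.00305 to 0.160 across the fits run. Of 34 lists 13 passed camera with the preset correlation and none with an estimated correlation, at adjusted p between 0.534 and 0.674; fry, which asks whether the genes of a list move on balance in 1 direction, passed 6, among them the mesenchymal transition and cell cycle genes (adjusted p = 0.012 each).

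Anti-PD-1 alone was compared with control. Lars2, the mitochondrial leucyl-tRNA synthetase, fell by 1.95 on the log2 scale (SE 0.22, edgeR adjusted p = 0.032, n = 3 and 3), from 364 ± 83.3 to 94.1 ± 19.5 CPM, and was the only gene of 17426 to pass. Lars2 also lay below the control libraries in the other treated groups, at 119 ± 14.3 CPM with entinostat and 113 ± 15.5 with the combination. Pdcd1, which encodes PD-1, stood at 0.26 ± 0.34 CPM in the control group and 0.55 ± 0.41 with anti-PD-1, and Cd274 at 2.91 ± 1.42 and 4.30 ± 0.62. Of the 24 cell cycle genes none passed over all genes, and 9 were lower when adjusted over the list alone. Cytotoxic and NK cell genes had a median log2 fold change of 1.47 over 9 genes and interferon response genes 0.55 over 24. T cell markers had a mean log2 CPM of −0.75 ± 0.60 in the control group and −0.31 ± 1.17 with anti-PD-1. The cytotoxic and NK cell genes were near the floor, at −2.60 ± 0.85 and −1.30 ± 0.36 in the same order. Medians were also high for erythroid (1.65), neutrophil (1.39) and B and plasma cell markers (0.99). No member of these lists passed the threshold. At an unadjusted p under 0.05 there were 2691 genes, and DESeq2 called 704. Lars2 did not pass without control library 1 (adjusted p = 0.091), control library 3 (0.056) or anti-PD-1 library 1 (0.079), 2 (0.227) or 3 (0.135), nor without any 1 of the 6 libraries of the other groups, which share the estimate of the spread (smallest adjusted p of any gene 0.059 to 0.099), over a range of 7.85e-12 to 0.466 across all fits run. Of 34 lists 10 passed camera with the preset correlation and none with an estimated correlation, at adjusted p between 0.490 and 0.767.

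The effect of entinostat in mice that also received the antibody was read from the combination against anti-PD-1. No gene passed in edgeR, against 2168 at an unadjusted p under 0.05 and 424 in DESeq2. The smallest p-values were those of the histone gene Hist4h4, at 538 ± 87.0 CPM with anti-PD-1 and 217 ± 35.3 with the combination (log2 fold change −1.31, SE 0.18), the collagen gene Col11a1, at 6.53 ± 3.16 and 41.9 ± 12.5 CPM (2.68, SE 0.40), and Lsm7, an RNA-processing protein, at 195 ± 16.1 and 86.4 ± 17.0 CPM (−1.17, SE 0.19), each with an adjusted p of 0.201 (n = 3 and 3). Histone genes have near-identical copies, so reads of Hist4h4 are uncertain. Hist4h4 lay between 341 and 382 CPM in the control group, so it was highest in the anti-PD-1 libraries. Those libraries also held the most reads from structural RNAs, and a link between both was not tested. Myc had a log2 fold change of 0.75 (SE 0.31) and Yap1 of 1.66 (SE 0.55), with adjusted p of 0.369 and 0.273. Neuronal differentiation genes had a median of −0.81 and neuroendocrine genes of −0.68, with 2 members of each lower when adjusted over the list alone. Markers of other cells moved too, with medians of 0.75 for macrophages and monocytes, 0.66 for fibroblasts and matrix, 0.64 for alveolar epithelium and 0.47 for endothelium. Of 34 lists 7 passed camera with the preset correlation and none with an estimated correlation, at adjusted p between 0.692 and 0.959.

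The effect of the antibody in mice that also received entinostat was read from the combination against entinostat. No gene passed in edgeR, against 270 at an unadjusted p under 0.05 and 1 in DESeq2. Sox5 stood at 12.2 ± 9.03 CPM with entinostat and 2.45 ± 0.15 with the combination (log2 fold change −2.31, SE 0.59), and Ret at 0.99 ± 0.18 and 3.24 ± 0.63 CPM (1.71, SE 0.48); both had an adjusted p of 1 (n = 3 and 3). Spaca1, also among the 3 smallest p-values, had no count in any entinostat library and averaged 0.75 ± 0.88 CPM with the combination. Interferon response genes had a median log2 fold change of 0.94 over 24 genes and MHC class I genes 0.46 over 19, with no member past the threshold. Both were among 9 of 34 lists that passed camera with the preset correlation, at adjusted p = 0.697 with an estimated correlation. B and plasma cell markers had a median of 1.26 and MHC class II genes of 0.63. Combination library 2 stood apart, at a mean log2 CPM of the interferon genes of 2.75 against 1.66 and 0.88 in combination libraries 1 and 3.

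Over both strata, the antibody effect compared 6 libraries with anti-PD-1 and 6 without. No gene passed in edgeR, against 1886 at an unadjusted p under 0.05 and 103 in DESeq2. Lrp1, an endocytic receptor, had a log2 fold change of 0.96 (SE 0.13), Nudt5, a nucleotide hydrolase, of −0.65 (SE 0.10) and Lars2 of −1.01 (SE 0.15), each with an adjusted p of 0.178 (n = 6 and 6). Interferon response genes had a median of 0.94 and MYC and ribosome biogenesis genes of −0.42, with 5 members of the second lower when adjusted over the list alone. Of 34 lists 5 passed camera with the preset correlation and none with an estimated correlation, at adjusted p between 0.466 and 0.770.

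Whether entinostat acted differently with and without the antibody was tested as an interaction. No gene passed in edgeR, against 1052 at an unadjusted p under 0.05 and 60 in DESeq2. The smallest p-values were those of the small nucleolar RNA Snord104 (log2 difference −2.05, SE 0.31), the Cajal body RNA Scarna6 (−2.43, SE 0.37) and Lars2 (1.88, SE 0.31), with adjusted p between 0.284 and 0.303. Small RNAs can lie inside other genes, and without a stated strand setting their reads cannot be told apart from those of an overlapping gene. Immediate early and stress genes had a median difference of −0.76 over 17 genes and cell cycle genes of 0.39 over 24, with no member past the threshold. Genes called for entinostat against control but not for the combination against anti-PD-1 are therefore not shown to differ between the strata.

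Across the 17426 genes, the log2 fold changes of entinostat against control and of the combination against anti-PD-1, which share no library, had a Pearson correlation of 0.468. The corresponding correlation of both antibody effects, without and with entinostat, was 0.137. Genes are not independent replicates, so these values carry no p-value across genes. The effects of entinostat and of anti-PD-1 against the same control libraries had a correlation of 0.659, against 0.595 in simulations of unchanged groups with those controls, and a covariance of 0.413 against 0.317 simulated (100 simulations). The simulations drew each gene independently, while genes in these libraries can shift together, so they give no scale for judging the excess. With 3 controls no split into groups of at least 2 libraries was possible, so part of the excess may come from the shared controls.

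**Figure D3:**
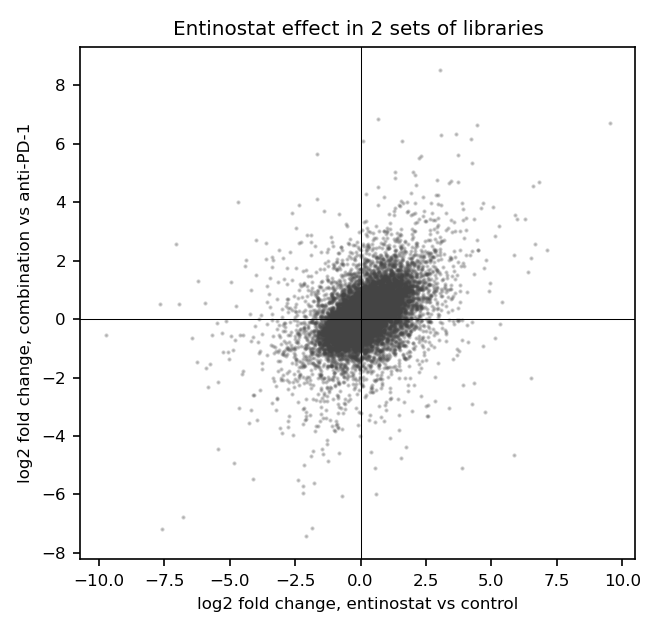
Log2 fold change of entinostat against control (horizontal axis) and of the combination against anti-PD-1 (vertical axis), with 1 point for each of the 17426 tested genes. The cloud leans upward to the right, at a Pearson correlation of 0.468 across genes.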

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

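No group had the 4 libraries that a check for outlying samples needs, so the results below stand out because the effect of entinostat differed with and without the antibody. They rest on camera with a preset correlation, none passed with an estimated correlation, and no gene passed the interaction test. Values are the mean over a list of the entinostat effect with anti-PD-1 minus that without it, on the log2 scale. Cytotoxic and NK cell genes had a difference of −1.36 (adjusted p = 0.022, or 0.809 with an estimated correlation). Their mean log2 CPM lay between −2.60 and −1.30 over the groups, so low counts carry that difference. Neutrophil markers had −0.60 (0.022, or 0.809) and alveolar epithelial markers −0.73 (0.026, or 0.809). Airway epithelial markers had −0.35 (0.032, or 0.809). Immediate early and stress genes had −0.82 (0.0017, or 0.371), and cell cycle genes 0.37 (0.010, or 0.809). Of 100 splits of the libraries within each stratum, 75 gave as many lists as the 6 found here, with up to 20 in another split, so chance can account for this number.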

How the results depend on the processing

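The fits without the structural RNAs, with their share or high Xist as a covariate, with halved counts, with thinned counts and with length and GC trends removed were chosen after seeing the data; the other alternatives were fixed before the data were examined. Under RLE factors, halved counts, thinned counts and without the structural RNAs, each count of changed genes stayed within 1.5 times. The cause was not tested for any change given here, except that the fits of only 2 groups and those without a library rest on fewer samples. DESeq2 called 2396 genes for entinostat against control, 704 for anti-PD-1 against control, 3591 for the combination against control, 424 for the combination against anti-PD-1, 1 for the combination against entinostat, 3422 for the entinostat main effect, 103 for the anti-PD-1 main effect and 60 for the interaction. Upper quartile factors called 561 genes for entinostat against control, and 2 lists for anti-PD-1 against control, 7 for the combination against control, 6 for the entinostat main effect and 2 for the interaction. With the alveolar score as a covariate, 0 genes passed for entinostat and 0 for anti-PD-1 against control, 300 for the combination against control, 1 for the combination against anti-PD-1 and 252 for the entinostat main effect. The same covariate left 4 lists for entinostat against control, 2 for anti-PD-1 against control, 5 for the combination against control, 4 for the entinostat main effect and 3 for the anti-PD-1 main effect. No value is given for the alveolar list itself there, since the covariate is its own mean. With only the 2 groups in the fit, 0 genes passed for each of the 3 comparisons against control and 3 for the combination against anti-PD-1. With the structural RNA covariate, 79, 0 and 238 genes passed for entinostat, anti-PD-1 and the combination against control, and 44 for the combination against anti-PD-1. With length and GC trends removed, 515 genes passed for entinostat against control. With the high Xist covariate, 0 passed for anti-PD-1 and 1069 for the combination against control. Without the filter, 4 lists passed for anti-PD-1 against control, and the correlation of the entinostat effects was 0.272 and that of the antibody effects 0.0541; Spearman's rho was 0.525 and 0.185. With an estimated correlation, 0 lists passed in each of the 8 comparisons. Fry passed 6 lists for the combination against control, 4 for the entinostat main effect and 0 in each of the others.

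With the replicate number as a block, 321 genes passed for entinostat, 0 for anti-PD-1 and 1087 for the combination against control, and 974 for the entinostat main effect. The numbers share no animal that the labels name. Same-numbered libraries did not deviate together, with a mean correlation of −0.015 over 18 pairs (range −0.292 to 0.226), and 1 of 12 libraries correlated best with its own number.

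Leaving out in turn each library of the groups compared gave from 2 to 1010 genes for entinostat against control, 310 to 1804 for the combination against control, 617 to 2070 for the entinostat main effect, 0 to 2 for anti-PD-1 against control and 0 in each fit of the other 4 comparisons. Libraries of the other groups, which share the estimate of the spread, moved entinostat against control to between 573 and 989 genes and the combination against control to between 1398 and 2066. Lists that passed ranged from 4 to 13 for entinostat, 2 to 15 for anti-PD-1 and 6 to 20 for the combination against control, 3 to 11 for the combination against anti-PD-1, 3 to 17 for the combination against entinostat, 5 to 13 for the entinostat main effect, 3 to 17 for the anti-PD-1 main effect and 3 to 12 for the interaction. The correlation of the entinostat effects ranged from 0.361 to 0.493 and that of the antibody effects from 0.062 to 0.200.

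For single genes, 2984 refits of 129 results gave 2236 on the same side of the threshold, 727 that lost and 20 that gained it. In 1 the sign turned: Myc in anti-PD-1 against control, which did not pass, went to −0.478 with the structural RNA covariate. For lists, 897 refits of 70 results gave 678 on the same side and 218 that lost the threshold, and the camera direction of the neuronal differentiation genes in the combination against entinostat turned to up without combination library 1, at a mean of −0.0308, over a range without single libraries of −0.623 to −0.0308. Myc against control lost its call with the replicate block too, at adjusted p of 0.058 for entinostat and 0.059 for the combination. Its log2 fold changes there, 1.53 and 1.26, hardly moved. Myc in the entinostat main effect stayed past the threshold in each alternative, at 1.02 to 1.31. Thinning the libraries to an equal total over the tested genes left 1835 genes for that effect, and to an equal total outside the structural RNAs 1762. Halving every count left 1872, so thinning could hardly have lowered the count much. The number of reads itself thus hardly bore on the count. A difference in preparation that goes with the greater depth of the control libraries was not tested by thinning.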

Other observations

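The tests chosen only after the result was seen were those of gene families, of length and GC content, of the structural RNA covariate, of the change between the combination and anti-PD-1 in genes called for entinostat, of other splits for the agreement of effects, and the comparison of control library 1 with other left-out libraries. Families were formed from the letters that begin a symbol, which gave 199 with at least 10 tested genes. Between the libraries with and without entinostat, 17 of 48 Mrpl genes and 12 of 29 Mrps genes, which encode mitochondrial ribosomal proteins, fell and none rose. Among subunits of respiratory complex I, 8 of 10 Ndufb and 8 of 14 Ndufa genes fell and none rose. Of 77 genes with the Hist symbol 30 fell and none rose, and histone genes have near-identical copies and often lack a poly(A) tail, so their counts are uncertain. Of 43 collagen genes 6 rose and none fell. Under upper quartile factors the counts that fell were 5 Mrpl, 6 Mrps, 6 Ndufb, 6 Ndufa and 20 Hist genes, and 7 collagen genes rose; with length and GC trends removed they were 9, 8, 6, 8 and 23, and 3 collagen genes rose. No family passed camera with an estimated correlation (adjusted p of 0.400 to 0.429 for these 6), while fry gave adjusted p of 0.0054 to 0.011. MicroRNA genes turned with the correction, from 9 of 340 higher and 1 lower to 2 higher and 5 lower.

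Lars2, the gene that passed for anti-PD-1 against control, lay between 300 and 458 CPM in the control libraries and between 76.7 and 130 CPM in the 9 treated ones.

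For the 1849 genes that differed with and without entinostat, 3 technical differences between libraries were modelled or removed in turn, since the libraries differed in alveolar markers, structural RNAs and the level of long transcripts. The median ratio of the log2 fold changes after and before was 0.962 with the alveolar score as a covariate, 1.04 with the structural RNA percent and, over the 1774 genes with a length, 0.932 with length and GC trends removed. All lie above the 0.5 written down before these ratios were first computed. For the alveolar score this shows only that the called genes did not follow the score within groups. The score varied widely there (SD 2.68 in the control group), so genes that followed it were unlikely to be called. None of its 16 markers passed. The ratio over called genes thus does not exclude it as a cause. The other 2 ratios could hardly have fallen under 0.5 and decide nothing. The structural RNA percent averaged 11.4 and 27.5 in the groups without entinostat and 17.8 and 17.9 in those with it, so it was nearly balanced. The median log2 fold change ran only from −0.10 in the quartile of shortest transcripts to 0.16 in that of the longest. The alveolar covariate still ended most calls, leaving 240 of the 1849, at a median size of 0.81 (median SE 0.22) after 0.83 (0.19) without it, and the length correction left 1263 of them at a median of 0.76 (SE 0.18; before the centring added later, its ratio was 0.997). Only the real split among 100 gave as many genes (highest other 1). That makes chance unlikely for this count, provided that each library is a separate sample, which the labels do not state. An effect of the drug on tumour or stroma is a hypothesis that may account for the count, with the makeup of the tissue, alveolar cells included, left open.

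The second pattern is that 919 genes differed between entinostat and control and 0 between the combination and anti-PD-1 in edgeR (2168 at an unadjusted p under 0.05, 424 in DESeq2), while the interaction test called 0 in edgeR (1052 at an unadjusted p under 0.05, 60 in DESeq2). A technical difference of the control libraries from all treated ones stays open. In the 919 genes the combination moved from anti-PD-1 by a median of 0.47 in the same direction, 0.426 of the 1.10 between entinostat and control, and 861 had the same sign, but another of the 10 splits reached 0.314. One distant control library stays open too: without control library 1 the count was 250, which met what had been written for that cause, yet it was 550 and 1010 without control libraries 2 and 3 and 204, 42 and 2 without entinostat libraries 1, 2 and 3, so control library 1 was not the one on which the count rested most. A weaker drug effect beside the antibody is a biological alternative that the design names and that these values cannot separate from both.

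The third pattern is the rise of Myc with entinostat, 1.14 (SE 0.22) on the log2 scale, while 4 genes of the MYC and ribosome biogenesis list fell; that list had a median of −0.60 with anti-PD-1 alone and −0.09 for the combination against anti-PD-1, with no member past the threshold in either. More normal lung in the entinostat libraries would lower the estimate once alveolar markers are modelled, and it was 1.27. This argues against that explanation. A fault of scaling stays open: the lower of the RLE and upper quartile estimates was 1.13, but these factors moved the median of all genes from 0.02 to 0.02 and 0.15, so neither could have lowered Myc by its SE. The counts do not separate the induced allele from the endogenous one, so whether the drug may act on either stays a hypothesis without a test here.

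Other splits of the libraries were counted for the remaining comparisons. Splits of 3 against 3 number 10, too few for a share under 0.05. For entinostat against control, 1 of 10 gave as many genes (919, highest other 1) and 6 as many lists (9, highest other 22). For anti-PD-1 against control, 2 gave as many genes (1, highest other 6) and 7 as many lists (10, highest other 16). For the combination against control, 1 gave as many genes (2033, highest other 0) and 4 as many lists (13, highest other 22). Both comparisons with 0 genes had 10 of 10 by definition (highest other 0 against anti-PD-1 and 1 against entinostat), and 7 and 3 splits gave as many lists (7 and 9, highest other 15 and 17). Of 100 splits within strata, 45 gave as many lists for the entinostat main effect (11, highest other 20) and 84 for the anti-PD-1 main effect (5, highest other 20), so chance is not excluded for these list counts. The anti-PD-1 main effect called 0 genes, so 100 of 100 gave as many by definition (highest other 46). For the interaction 100 of 100 gave as many genes, again by definition (0, highest other 1849); that other split exchanges treated and untreated libraries in 1 stratum and so measures the entinostat main effect. The agreement of the entinostat effects, 0.468, was reached by 1 of 100 splits, the real one (highest other 0.355). That makes chance unlikely, again provided that each library is a separate sample. The agreement of the antibody effects, 0.137, was reached by 15 of 100 (highest other 0.444), so chance is not excluded for it.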
